A study of Lactiplantibacillus plantarum WCFS1 with 11 samples.

How the data were processed

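Total RNA of Lactiplantibacillus plantarum WCFS1, a lactic acid bacterium, was compared on 11 two-colour arrays. Per the labels' protocols, the cells came from a pH-controlled batch culture in CDM broth that was sampled at different optical densities (OD600), and cDNA was made from total RNA with an oligo(dT)-type primer and labelled with Cy3 or Cy5. The labels name 8 sampling points: OD600 of 1.5, 3.0, 5.0, 5.1, 5.2, 5.3 and 5.4, written OD1.5 to OD5.4 here, and a sample taken at 24 h. Of the 11 arrays 10 set the RNA of 1 point in Cy5 against that of another in Cy3, per the labels. A single RNA sample is named per point and no separate cultures are named, so no p-value here measures the spread between cultures. The p-values of single targets measure the spread between hybridisations, with a further limit for 24 h given below. Those for groups or for the order of targets compare targets with each other.

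The arrays formed a loop of 3 triangles, OD1.5 with OD3.0 and OD5.0, OD5.0 with OD5.1 and OD5.2, and OD5.2 with OD5.3 and OD5.4. In each triangle every point was labelled with Cy5 once and with Cy3 once. A further array joined OD5.4 to 24 h, and the last held 24 h RNA in both dyes. The arrays lay on 4 slides. Slide 1 held 3 arrays with the longer hops OD1.5 to OD5.0, OD5.0 to OD5.2 and OD5.2 to OD5.4, and slide 2 held 6 arrays with every step from OD1.5 to OD5.4.

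For each array the deposited file gives spot and local background intensity in each dye as means, neither background-subtracted nor normalized, per the file headers, with a flag code whose meaning the files do not state. The deposited series table gives log2 ratios. Set against the scanner values, they were log2 ratios of background-subtracted signals with an intensity-dependent shift made by the authors. They ran as Cy3 over Cy5 on 9 arrays and as Cy5 over Cy3 on the 2 arrays with 24 h RNA. The medians of the 11 columns lay between -0.13 and 0.05. The values were blank exactly where a dye was at or below its local background. The scanning and spot-reading software, its version and the normalization method are not given in the sources used here. The series table served only as an alternative, turned to Cy5 over Cy3.

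Each array held 9271 spots. Of these 60 were controls and 36 had IDs starting with mtf, whose target the files do not state. Both kinds were left out of the tests. The other 9175 probes belonged to 3096 targets, of which 3032 carry an lp_ tag with a number, and 3022 had 3 probes. The remaining IDs name 14 tRNAs, 3 other RNAs, 3 antisense probes and 3 numbered series, called p1, p2 and p3 after their IDs. The files do not pair the tags with gene names. The reference table of 3031 genes used here is of another strain, and 0 of the IDs matched it. The gene lists fixed before the data were examined select members by gene symbol, so none of them was tested, and no gene function is given.

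The background was corrected with normexp (offset 50) on all spots, and each array was normalized by loess with weight 0 on control and mtf spots (limma 3.58.1, R 4.3.3). The files hold no call of a signal well above background and no spread of the local background of a spot. A spot was therefore counted as above background where its mean exceeded the array's median local background by 2 robust SDs (scaled median absolute deviation) of the local backgrounds in that dye. Probes above background in either dye on at least 3 arrays were kept (8210 probes, 2931 targets), and the probes of a target were averaged. A target counted as below background at a point when none of its kept probes passed in any channel of that point. Changes of such targets are given as "at least N-fold". That bound sets the mean level of the brighter point against the higher of the dim probe's own level and the lowest level among probes above background, per channel after loess and Aquantile scaling. It does not go through the loop fit, is open to dye bias and holds for this processing alone. For lp_1290, lp_3548 and lp_p3_05 the dim probes' own level was the higher, so the bound is the plain difference of the levels. Without background correction the fitted log2 changes were lower than the bound for lp_1290 (4.95), lp_3548 (5.09) and lp_p3_05 (3.23). No bound is given for lp_2450, where it lay above the fitted change.

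The log2 ratios (Cy5 over Cy3) were fitted with limma's lmFit and eBayes in 1 model of all 11 arrays, with a coefficient for each point and a dye term for each target. The model left 3 residual degrees of freedom per target. The prior of eBayes added 5.78, with a prior SD of 0.25 log2. The comparisons were OD5.0 against OD1.5, OD5.4 against OD5.0, 24 h against OD5.4 and the 6 successive steps of growth, with an F test over all points. Targets with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Since loess centres the log ratios of each array, rises and falls are relative to the typical target and do not measure total RNA. Groups of targets were compared with the rest by limma's camera, with an inter-gene correlation preset at 0.01 and again with an estimated one. The median SE was 0.20 log2 for the steps and OD5.0 against OD1.5, 0.28 for OD5.4 against OD5.0 and 0.25 for 24 h.

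By the rule fixed before the data were examined, a target without a symbol is named only where it holds the largest rise or fall among the calls of a comparison. That rank is by fitted value, and a target below background at a point has no exact value there, so its rank is not exact. Runs of neighbouring tags, meaning called targets with consecutive places in the order of the tag numbers and the same direction, were chosen after their values were seen and are named by their first tag. The tRNA and p3 groups were likewise taken from the IDs after the data were seen.

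The fit was tested on simulated log ratios of the same design, 2931 targets with 200 of them changed in each comparison. Of targets changed 2-fold it called 70.1% for OD5.0 against OD1.5, 8.96% for OD5.4 against OD5.0 and 32.8% for 24 h against OD5.4. Of those changed 4-fold it called 100%, 92.4% and 92.4%. In the data 1078, 1796 and 1356 targets were called, far more than the 200 changed in the simulation. The share called after Benjamini-Hochberg adjustment depends on how many targets change, so these percentages do not give the power of the comparisons. All simulated arrays of a target had the same noise, and that of the array linking 24 h was not measured.

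The alternatives were no dye term, no background correction, the series table, median centring in place of loess, no filter, a strict filter (above background in both dyes on all 11 arrays), eBayes with trend and robust, the median of a target's probes, array weights, slide as a random block, the 24 h self hybridisation left out and each array left out in turn. A filter on the flag codes, a fit without both arrays of 24 h RNA and a 24 h comparison on bright targets alone were added after seeing the data. With a fixed term for each slide, 2 residual degrees of freedom would be left, but the slide terms are aliased with the sampling points and 0 of the 9 comparisons could be estimated. Figures were drawn with matplotlib 3.10.9.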

Results

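The 11 arrays followed the transcriptome of L. plantarum WCFS1 over 8 sampling points of a batch culture, from OD1.5 to OD5.4 and at 24 h. OD5.0 and OD5.2 were each read in 4 channels, OD5.4 and 24 h in 3 and the other points in 2. The median signal over local background was 4.98 ± 0.273 at OD1.5 (SD, n = 2 channels), 5.54 ± 0.312 at OD5.0 (n = 4) and 5.36 ± 0.669 at OD5.2 (n = 4). It was lower at OD5.3 (3.25 ± 0.263, n = 2), OD5.4 (2.13 ± 0.203, n = 3) and 24 h (1.21 ± 0.107, n = 3). The brightest 1% of probes held 4.19% ± 0.0451 of the signal at OD1.5, 5.87% ± 0.101 at OD5.3, 11.2% ± 1.10 at OD5.4 and 38.2% ± 8.55 at 24 h. At least 1 kept probe was above background for 2484 of the 2931 tested targets at OD1.5, 2825 at OD5.4 and 2789 at 24 h. These counts take any channel of a point, of which OD1.5 had fewer, and the limit differed between channels. They therefore do not show that more targets were present late. Per channel, 73.8% ± 1.39 of the target probes were above background at OD1.5, 71.4% ± 11.0 at OD5.4 and 57.3% ± 5.58 at 24 h.

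**Figure D1:**
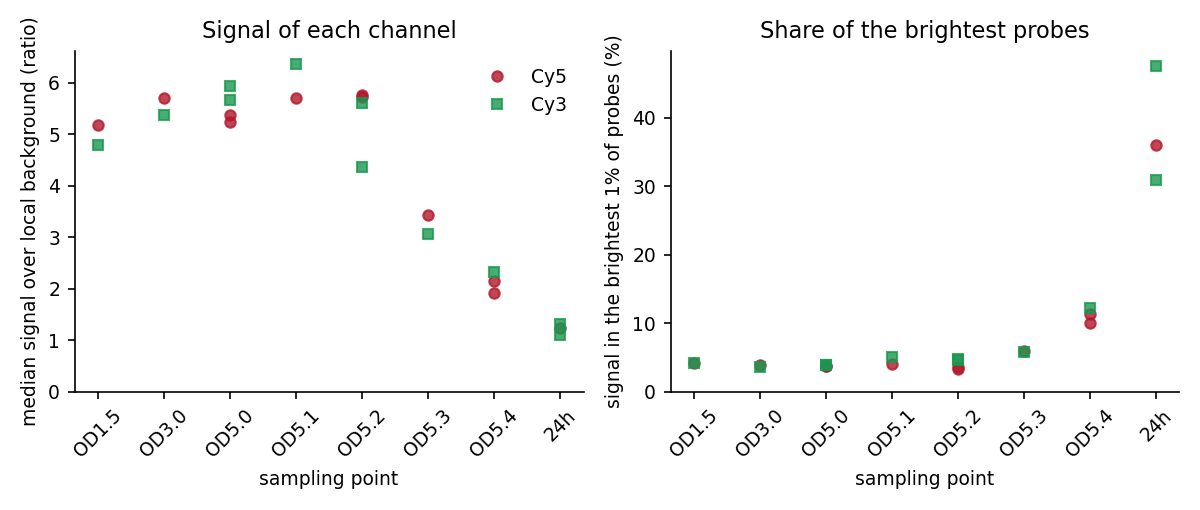
Each symbol is 1 channel of 1 array, with the dye by colour and shape. The left axis gives the median ratio of signal to local background of the target probes, which ran from 6.36 in an OD5.1 channel to 1.09 in a 24 h channel, and the right axis gives the percent of background-subtracted signal in the brightest 1% of probes, up to 47.6% at 24 h.

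Channels labelled as the same growth point resembled each other. The rank correlation of the probe signals averaged 0.964 over 19 pairs of channels from different arrays with the same growth point, and 0.773 over 143 pairs with different points. The 24 h channels of the 2 arrays correlated at 0.774 (2 pairs), against 0.622 with OD5.4 (8 pairs). With the dyes of every array exchanged, the same-point value was 0.781. The sum of the log ratios round each triangle, less the dye term, had an SD over targets of 0.43, 0.41 and 0.51 log2. Turning the sign of any array of a triangle raised it to 1.13 or more. The dye term was past the threshold for 0 targets by limma, with 345 at an unadjusted p under 0.05. Its SD over targets was 0.13 log2, and the log ratio of the 24 h self hybridisation had an SD of 0.29.

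Over the whole curve, 2665 of 2931 targets differed between sampling points by limma's F test. Of these, 2612 spanned at least 2-fold between their highest and lowest point. The highest level fell at 24 h for 683 of them, at OD5.3 for 389 and at OD1.5 for 350. The lowest level fell at 24 h for 673, at OD5.3 for 395 and at OD1.5 for 386. OD5.1 held the fewest extremes, with 169 highest and 168 lowest levels. The 24 h levels rest on a single linking array. Over the growth points alone, 2371 targets spanned 2-fold, and OD5.4 held the highest level for 573 and the lowest for 471, against 198 and 187 with 24 h included.

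Between OD1.5 and OD5.0 the largest rise by fitted value was that of lp_1290. It was below background at OD1.5 and, in the main processing, at least 53.9-fold higher at OD5.0 (fitted log2 change 6.03, SE 0.17, adjusted p = 2.92e-07). Without background correction its fitted log2 change was 4.95, below that bound. All changes are given as the later point over the earlier, from ratios of Cy5 over Cy3, where the deposited log2 table runs as Cy3 over Cy5 on 9 of the 11 arrays. A run of 12 neighbouring tags from lp_2718 rose together, by 4.82 to 5.62 log2 (mean 5.16, SD over genes 0.29). The largest fall was that of lp_2033 (log2 change -3.50, SE 0.18, adjusted p = 5.37e-06). The longest run that fell held 11 tags from lp_1175, with a mean log2 change of -1.21 (SD over genes 0.35), and 3 of these 11 were called without the OD1.5 over OD5.0 array. In all 1078 targets changed, 514 up and 564 down, of which 210 rose and 253 fell at least 2-fold. Of the rises 96 were below background at OD1.5, and of the falls 57 were below it at OD5.0, so their changes have no exact value. The change of lp_2033 was -3.43 on slide 1 and -3.63 on slide 2. Over all targets the 2 slides correlated with r = 0.816. With slide as a random block 979 targets changed. Without the OD1.5 over OD5.0 array, the direct one, 286 did (144 up, 142 down), and the strict filter turned the majority (242 up, 178 down), as did the series table (223 up, 208 down).

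The same 2 runs had the longest changes in both steps of this interval, in opposite directions. From OD1.5 to OD3.0, lp_2703 rose most (log2 change 4.87, SE 0.28, adjusted p = 3.10e-05), inside a run of 9 tags from lp_2696 with a mean rise of 3.97 (SD over genes 0.93). The largest fall was that of lp_1682 (log2 change -3.19, SE 0.24, adjusted p = 8.84e-05), inside a run of 16 tags from lp_1670 with a mean of -2.38 (SD 0.45). From OD3.0 to OD5.0 each changed the other way. The tags from lp_1670 rose by a mean of 2.61 over 13 genes, and those from lp_2696 had a mean change of -2.90 over 10 genes, with lp_2703 again the largest single change downwards (log2 change -3.94, SE 0.28, adjusted p = 3.41e-05). The largest rise of that step was lp_2719, in the run from lp_2718 (log2 change 6.04, SE 0.30, adjusted p = 7.88e-06). At OD3.0 the 12 tags of this run stood at a mean of only 0.49 log2 above OD1.5 (SD over genes 1.35). The first step changed 484 targets (220 up, 264 down) and the second 909 (448 up, 461 down), where the majority turned in 9 of 24 alternatives. Slide 2 held the direct array of every step of growth. Without it, 79 and 211 targets changed. Both steps share the single RNA sample of OD3.0, read on slide 2 alone. An error in that sample would move them in opposite directions. Over all targets their log2 changes correlated at -0.309 (covariance -0.162), against -0.494 (covariance -0.0240) in 100 simulations of no effect. Handling of the OD3.0 sample and a brief real shift therefore cannot be told apart.

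**Figure D2:**
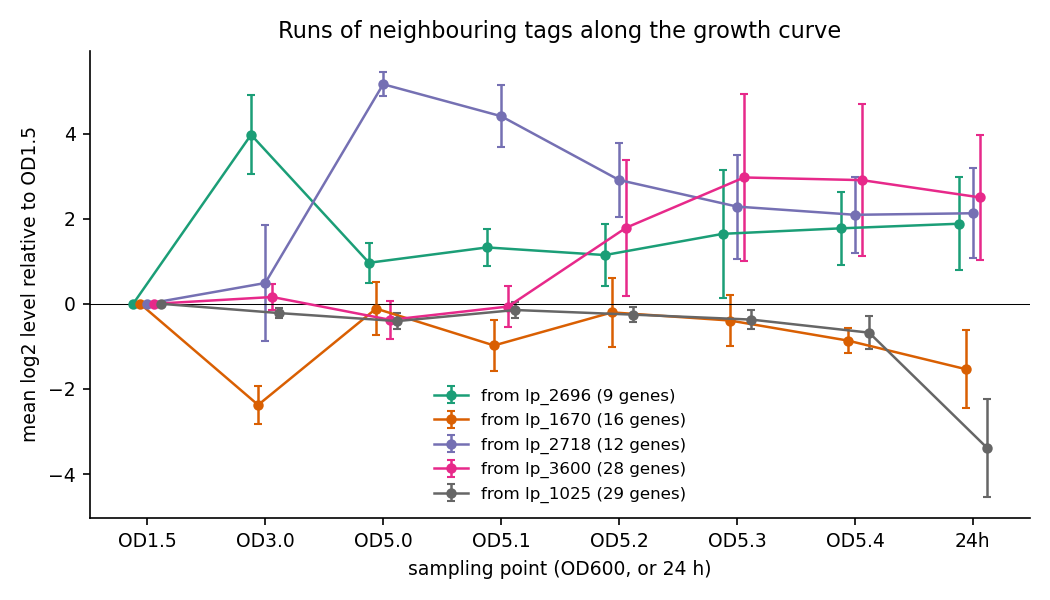
Mean log2 level of 5 runs of neighbouring tags at each of the 8 sampling points, relative to OD1.5, with the SD over the genes of a run as error bars. The run from lp_2696 peaked at OD3.0 (3.97), where the run from lp_1670 was lowest (-2.38), the run from lp_2718 peaked at OD5.0 (5.16), and the run from lp_1025 fell at 24 h (-3.38).

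Between OD5.0 and OD5.4 lp_1912 rose most by fitted value. It was below background at OD5.0 and at least 96.6-fold higher at OD5.4 (fitted log2 change 8.26, SE 0.25, adjusted p = 4.76e-07). A run of 28 tags from lp_3600 rose together, by 0.64 to 6.52 log2 (mean 3.28, SD over genes 1.76). The largest fall was that of lp_2718 (log2 change -4.86, SE 0.24, adjusted p = 1.86e-06, between -5.65 and -3.27 over the alternatives). It starts the run of 12 tags that had risen before OD5.0. All 12 fell (mean log2 change -3.07, SD over genes 0.76), and at OD5.4 they stood at a mean of 2.09 log2 above OD1.5. In all 1796 targets changed, 942 up and 854 down, and 809 rose and 658 fell at least 2-fold. Of the rises 203 were below background at OD5.0, and of the falls 66 were below it at OD5.4. The changes of these targets, and means over runs that hold such targets, have no exact value. The change of lp_2718 was -5.18 on slide 1 and -4.21 on slide 2. Over all targets the slides correlated with r = 0.868. With slide as a random block 1594 targets changed. Without the OD5.0 over OD5.2 array 1011 did (633 up, 378 down), and median centring turned the majority (909 up, 999 down).

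**Figure D3:**
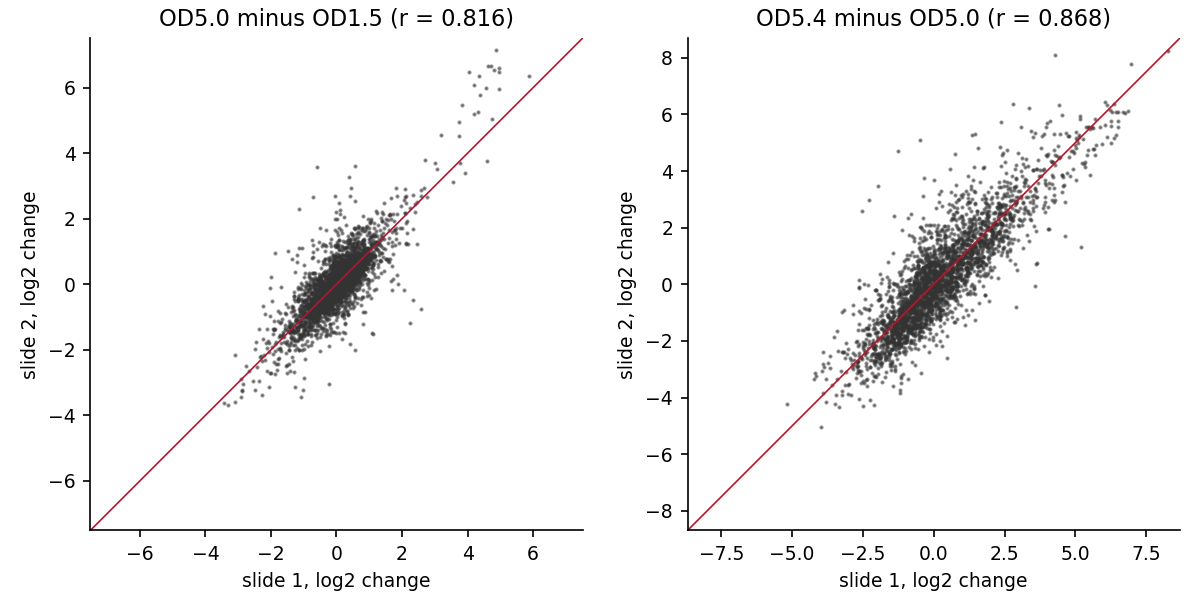
Each point is 1 of 2931 targets, with the log2 change on the arrays of slide 1 on the horizontal axis and on those of slide 2 on the vertical axis, neither corrected for dye, and the line marks equal changes. Pearson's r across targets was 0.816 for OD5.0 minus OD1.5 and 0.868 for OD5.4 minus OD5.0.

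Within that interval the changes were unevenly spread. From OD5.0 to OD5.1, 393 targets changed (242 up, 151 down). The largest rise was lp_2034 (log2 change 4.15, SE 0.19, adjusted p = 1.18e-05) and the largest fall lp_2718 (log2 change -2.55, SE 0.17, adjusted p = 5.32e-05, or limma adjusted p = 0.0739 in the series table). From OD5.1 to OD5.2, 928 changed (517 up, 411 down). The tag lp_3548 was below background at OD5.1 and, in the main processing, at least 52.4-fold higher at OD5.2 (fitted log2 change 6.27, adjusted p = 3.97e-07). Without background correction its fitted log2 change was 5.09, below that bound. A run of 12 tags from lp_3518 rose by a mean of 2.30 log2 (SD over genes 1.45), and lp_2526 fell by 3.79 log2 (SE 0.18, adjusted p = 1.17e-06). From OD5.2 to OD5.3, 1731 changed (897 up, 834 down, and 807 up, 941 down with median centring), the highest count of the 6 steps unless its direct array is left out (816, against 990 for OD5.1 to OD5.2). The target lp_p3_05 was below background at OD5.2 and, in the main processing, rose at least 17.7-fold (adjusted p = 9.92e-06), which does not rank it above targets measured at both points. Without background correction its fitted log2 change was 3.23, below that bound. A run of 19 tags from lp_2426 rose by a mean of 1.72 log2 (SD over genes 0.42). The target lp_2450 fell to below background at OD5.3 (adjusted p = 3.06e-06), with fitted log2 changes between -5.26 and -2.38 over the alternatives. From OD5.3 to OD5.4, 715 changed (360 up, 355 down), with the largest rise at lp_tRNA08 (log2 change 2.35, SE 0.33, adjusted p = 0.00422, 1 probe) and the largest fall at lp_1084 (log2 change -2.02, SE 0.18, adjusted p = 0.00191). Without the direct array of each step the counts were 25, 367, 816 and 2, in the order of the steps, and the changes of lp_tRNA08 (adjusted p = 0.105) and lp_1084 (adjusted p = 0.0959) no longer passed. The last step also had 160 calls with array weights and 0 in the series table, so the count of that step rests on its direct array and on equal weights.

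**Figure D4:**
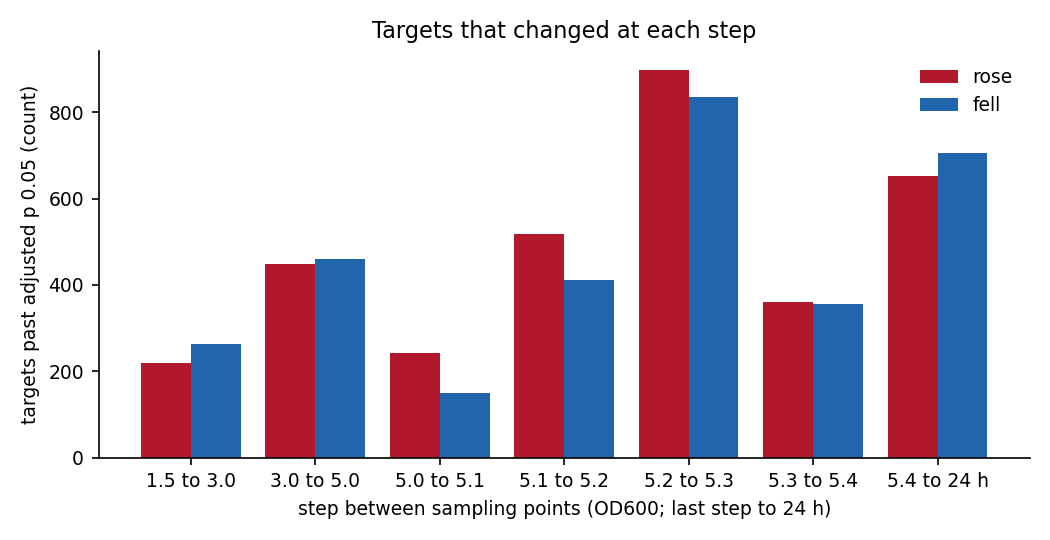
Bars give the number of targets past an adjusted p of 0.05 at each step between sampling points, red for rises and blue for falls, of 2931 tested. The step from OD5.2 to OD5.3 had the highest bars (897 and 834) and the step from OD5.0 to OD5.1 the lowest fall count (151).

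At 24 h, compared with OD5.4, lp_3286 rose most (log2 change 5.66, SE 0.37, adjusted p = 3.46e-05) and lp_1052 fell most (log2 change -4.57, SE 0.23, adjusted p = 2.01e-05). Over the alternatives these changes ran from 4.56 to 6.27 and from -5.82 to -2.55. The fall of lp_1052 was part of a run of 29 neighbouring tags from lp_1025 that fell together, with a mean log2 change of -2.71 (SD over genes 1.02). Through the whole of growth the mean level of these 29 tags had stayed within 0.68 log2 of OD1.5 (-0.68 at OD5.4). The longest run that rose held 8 tags from lp_1192, with a mean of 1.76 (SD over genes 0.96), of which 4 were called in the series table. In all 1356 targets changed, 651 up and 705 down, of which 439 rose and 467 fell at least 2-fold. After loess the median log2 change of all targets was 0.0088, so this split is relative to the typical target. Of the rises 24 were below background at OD5.4, and of the falls 32 were below it at 24 h, so their changes have no exact value. More rose than fell without background correction (702 and 566), under the strict filter (456 and 336) and among targets bright at 24 h (262 and 243). The strict filter and the bright set require signal above background at both points. They thus select on the levels compared, which can itself shift the split. This comparison rests on a single array with signals close to background, in 1 dye direction and without a repeat. Its SEs and p-values take their spread from the brighter growth arrays and the self hybridisation, so they do not measure the noise of that array. Probes of the same target differed in sign for 21.0% of the changed targets with several probes, against 2.03% for OD5.0 minus OD1.5 and 6.19% for OD5.4 minus OD5.0. With slide as a random block 1235 targets changed.

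Of the targets with p3 numbers 37 were measured, and more of them rose than fell during growth, while more fell than rose at 24 h. Between OD1.5 and OD5.0, 19 rose and 4 fell (20 and 5 adjusted over the list alone), with a median log2 change of 0.57 and camera adjusted p = 0.0105, or adjusted p = 0.275 with an estimated correlation. Between OD5.0 and OD5.4, 19 rose and 4 fell (19 and 5 adjusted over the list alone), with a median of 0.62 (0.24 to 0.81 over the alternatives) and camera adjusted p = 0.0527, or adjusted p = 0.415 with an estimated correlation. In that interval 14 targets with consecutive p3 numbers rose by a mean of 1.98 log2 (SD over targets 0.55). At 24 h, 2 rose and 21 fell (2 and 22 adjusted over the list alone), with a median of -0.88 (-1.87 to -0.43 over the alternatives) and camera adjusted p = 6.99e-05, or adjusted p = 0.0773 with an estimated correlation. Here 13 consecutive numbers had a mean change of -1.81 (SD 0.72). The 24 h values are relative to the typical target and rest on the single linking array, whose noise was not measured.

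Of 11 tRNAs measured, which carry amino acids to the ribosome, 9 rose and 0 fell at 24 h (10 and 0 adjusted over the list alone). These rises are relative to the typical target and do not show that the amount of tRNA grew. They rest on the single array linking 24 h, whose noise was not measured, and so do the camera p-values at 24 h. The median log2 change was 1.44 (0.88 to 1.94 over the alternatives), with a range over tRNAs of 0.38 to 2.57. Each tRNA had 1 or 2 kept probes, mostly 1, so agreement between probes could hardly be checked. Camera gave adjusted p = 6.99e-05, or adjusted p = 0.0773 with an estimated correlation. Between OD1.5 and OD5.0, 1 rose and 4 fell (median -0.35, camera adjusted p = 0.133, or adjusted p = 0.392 with an estimated correlation), with 1 and 5 adjusted over the list alone. Between OD5.0 and OD5.4, 4 rose and 3 fell (median 0.61, camera adjusted p = 0.589, or adjusted p = 0.744 with an estimated correlation), with 6 and 3 adjusted over the list alone. The sign of that last median turned under median centring (-0.16). Most of those 4 rising tRNAs were below background at OD5.0, so their changes have no exact value.

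Neighbouring tags changed together in every comparison. For OD5.4 against OD5.0, 506 of 2875 targets on the tag order lay in runs of at least 5 called in the same direction, against a mean of 58.5 and a maximum of 119 in 1000 shuffled orders. For OD5.0 against OD1.5 the count was 142 (shuffled maximum 25) and for 24 h against OD5.4 it was 183 (shuffled maximum 56). The correlation of log2 changes between adjacent tags was 0.4997, 0.518 and 0.375 in OD5.0 against OD1.5, OD5.4 against OD5.0 and 24 h against OD5.4. Each lay above all 1000 shuffled orders (permutation p = 0.001, one-sided, the smallest these orders can give). The longest rises of OD5.0 against OD1.5 and OD5.4 against OD5.0 (12 and 28 tags) and the longest fall at 24 h (29) exceeded those of all shuffled orders (9, 14 and 10). The longest fall of OD5.4 against OD5.0 (12 tags, shuffled maximum 13) and the longest rise at 24 h (8, shuffled maximum 9) did not. These are correlations across genes, which are not independent replicates.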

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

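The tests of a faulty array, of dim targets, of loess, and of hybridisation noise and sample handling at OD5.0 were chosen after the results they bear on had been seen.

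In the OD5.2 channel of the OD5.3 over OD5.2 array, the median signal over background was 4.37, far below the other 3 OD5.2 channels by the gap relative to the range. Of 8 such comparisons of 4 channels this was the one past the limit, and chance flags about 1 in 20 groups.

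Of 36 probes with IDs starting with mtf, which no comparison used, 32 (88.9%) were above background on at least 3 arrays. This was so for 10 of 60 control probes (16.7%) and for 8210 of 9172 target probes (89.5%, antisense probes left out). The mtf probes were thus above background about as often as target probes. The mean of the 12 such probes with IDs starting mtf_9rev rose between OD5.0 and OD5.4 by 1.12 log2 (SE 0.25, limma adjusted p = 0.0038), and between OD5.4 and 24 h by 0.79 (SE 0.22, adjusted p = 0.0192). The mean of the 4 mtf_gen probes, which mixes IDs with and without the ending rev, passed at 24 h alone (0.71, adjusted p = 0.0322). The mean of the 16 mtf_9 probes passed in none of these comparisons (-0.04 at 24 h, adjusted p = 0.901). What they target is not stated in the files.

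The step from OD5.2 to OD5.3 had the most calls of the 6 steps of growth (1731) for an OD600 difference of 0.1. A faulty array is argued against by the correlation of 0.824 across targets between the direct array and the path through OD5.4 on other arrays. Noise of the arrays with OD5.3 and OD5.4 RNA stays open for the count. The 1731 targets with the largest direct ratio had the same sign through OD5.4 in 91.6%. This share was at least 82.7% at each of the 6 steps, also at OD5.3 to OD5.4, so it bears on direction alone. Array weights were 0.54 for each array of the triangle OD5.2, OD5.3 and OD5.4, against 1.35 or 1.49 in the other triangles. The direct array also held the flagged OD5.2 channel. Among targets above background in both dyes on all arrays, the step from OD5.2 to OD5.3 still had the most calls, 725 against 386 for the next. With array weights its lead narrowed to 1426 against 1317 for OD5.1 to OD5.2, without its direct array it was lost (816 against 990), the time between samples is not given in the labels, and a change of growth phase is an open explanation that was not tested here.

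At 24 h, 1356 targets were called with a median signal over background of 1.31 for 24 h on the array that links it to growth. Of 858 targets with every probe above background in both dyes on that array, 465 were among these calls. With the model and its eBayes prior fitted anew, and p adjusted, over the 858 alone, 58.9% were called. Signals below that limit are thus not the whole cause of the calls. The limit lay close to background, at 1150 against a median local background of 920 in the 24 h channel. Signals little above it therefore stay open as a cause. A pull of abundant transcripts on loess as the whole cause is argued against by 1061 of the calls that median centring also made in the same direction, and stays open for the other 295. Dye bias of the size measured on the other arrays is argued against as the whole cause. The dye term had an SD of 0.13 log2 and the self hybridisation one of 0.29, with 14 targets at 2-fold, against 1.12 for the 24 h changes. Dye bias particular to the linking array stays open for all the calls. The self hybridisation correlated at -0.0917 with the linking array over called targets but, at 0.0164, did not follow the mean Cy5 over Cy3 ratio of the growth arrays either. Outside the 858 the probes of 26.8% of the called targets with several probes differed in sign, against 9.84% among the 465 and 2.03% for OD5.0 minus OD1.5. Background and real change therefore cannot be told apart outside the 858, and not fully within them. The noise of the single linking array was not measured, and no biological explanation was tested.

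Many changes into OD5.0 turned at OD5.1, though the channels of these points correlated at 0.948 and their step had the fewest calls of the 6 in the main fit. With array weights OD5.3 to OD5.4 had fewer (160 against 783). Of 393 targets called from OD5.0 to OD5.1, 258 had been called in the opposite direction from OD3.0 to OD5.0 and 11 in the same, where independent lists would share 61.1 and 60.7. The log2 changes of these steps correlated at -0.519 across targets (covariance -0.242), against -0.000512 (covariance -2.75e-05) in 100 simulations of no effect on these arrays. Noise of single hybridisations is argued against by a correlation of -0.406 between OD5.0 minus OD1.5 on slide 1 and OD5.1 minus OD5.0 on slide 2. Both arrays held OD5.0 in Cy3, so a dye effect would also lower that correlation. Rank correlations of OD5.0 channels were higher by only 0.00143 within a dye than between dyes. That difference cannot decide on dye bias, since the whole change to OD5.1 lowered the rank correlation only from 0.979 to 0.948. The fit takes out a constant dye effect (SD 0.13 log2), and dye bias beyond it stays open. Handling of the 1 RNA sample and a brief real shift of these 258 targets cannot be told apart, since the labels name no second sample of that point.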

How the results depend on the processing

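Signal over background limits the later points more than the earlier ones, since it fell from 4.98 at OD1.5 to 1.21 at 24 h. The planned run on the scanner software's processed signals was not made, since the columns used hold means only, and the gene lists were not run for want of names. Over all alternatives, 410 of 414 values of the named targets kept their direction and their side of the threshold. The other 4 kept their direction with adjusted p up to 0.105. None of 426 mean changes of the runs turned sign, with 403 within the spread over genes, but calls within runs were lost. Among runs not named here, 3 had 0 tags called in the series table and another 1 of 7. Named runs went down, outside the strict filter, to 3 of 11 (lp_1175), 8 of 12 (lp_2718, fall), 20 of 28 (lp_3600), 4 of 8 (lp_1192), 8 of 12 (lp_3518), 14 of 19 (lp_2426) and 10 of 13 (lp_1670, rise). The groups of p3 and tRNA targets kept sign and side in 112 of 125. Camera called the p3 rise from OD5.0 to OD5.4 under some settings, with adjusted p from 0.0116 to 0.312, and the tRNA fall from OD1.5 to OD5.0 without background correction, with adjusted p from 0.0270 to 0.688 over the settings. The dye effect had 0 calls with median centring and without the self hybridisation. Median centring lowered the median change of all targets from OD5.0 to OD5.4 to -0.17 from 0.03. Whether rises or falls held the majority turned under some setting in 6 of the 9 comparisons, not in OD1.5 to OD3.0, OD5.0 to OD5.1 or OD5.1 to OD5.2. Median centring made 1484 of the 1796 calls from OD5.0 to OD5.4 again in the same direction.

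Counts of calls moved by over 1.5 times in these cases, and the cause was not tested except where named. Without background correction there were 1638 (OD1.5 to OD5.0), 1086 (OD1.5 to OD3.0), 1477 (OD3.0 to OD5.0), 959 (OD5.0 to OD5.1), 1472 (OD5.1 to OD5.2) and 1196 (OD5.3 to OD5.4). The series table gave 431, 114, 397, 49, 431 and 0 for the same comparisons. At OD5.0 to OD5.1 its share of rises was 85.7%, against 61.6%. Median centring gave 310 for OD1.5 to OD3.0. Array weights gave 817 for OD1.5 to OD3.0, 783 for OD5.0 to OD5.1 and 160 for OD5.3 to OD5.4. The strict filter tested 1462 targets in place of 2931, which alone lowers counts. It also keeps only probes above background at every point, so its splits are those of a selected set. It gave 1263 over all points, 420 for OD1.5 to OD5.0, 764 for OD5.0 to OD5.4, 792 for 24 h, and 186, 355, 104, 275, 725 and 386 for the 6 steps in order. Its share of rises at OD5.3 to OD5.4 was 64.2%, against 50.3%. Of the 858 targets bright at 24 h, 505 were called in a fit of these targets alone.

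With each array left out in turn, counts ran from 2524 to 2654 over all points, 286 to 1177 for OD1.5 to OD5.0, 1011 to 1796 for OD5.0 to OD5.4 and 1210 to 1415 for 24 h. For the steps in order they ran from 79 to 502, 211 to 963, 25 to 436, 367 to 990, 816 to 1743 and 2 to 715. The lowest count of each step came without its direct array, which leaves the path over 2 arrays. Other moves beyond 1.5 times were 667 for OD1.5 to OD5.0 without OD3.0 over OD1.5 or OD5.0 over OD3.0, 277 for OD1.5 to OD3.0 without OD1.5 over OD5.0 or OD5.0 over OD3.0, 194 for OD5.0 to OD5.1 without OD5.0 over OD5.2 or OD5.2 over OD5.1, 575 for OD5.1 to OD5.2 without OD5.0 over OD5.2 or OD5.1 over OD5.0, and 422 for OD5.3 to OD5.4 without OD5.2 over OD5.4 or OD5.3 over OD5.2. The 24 h comparison has no value without its only array. The filter on flag codes and the fit without both 24 h arrays, chosen after seeing the data, moved no count by over 1.5 times.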

Other observations

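The overlaps of successive comparisons were chosen after the calls had been seen, and the test of position was not. Targets tended to keep their direction across OD5.2. Of those called from OD5.1 to OD5.2, 251 rose in that step and again in the next, where independent lists would share 158.2, and 159 fell in both, where they would share 116.9. A rise followed by a fall was seen for 95 (independent lists 147.1) and a fall followed by a rise for 79 (125.8). The log2 changes of these steps correlated at 0.205 across targets, against 0.00484 in 100 simulations of no effect.

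Of the targets called between OD5.0 and OD5.4, 272 rose in that interval and rose again by 24 h, where independent lists would share 209.2, and 263 rose and then fell, where they would share 226.6. Falls were followed by rises for 136 (independent lists 189.7) and by falls for 169 (205.4). The log2 changes correlated at -0.0333 across targets, against -0.00202 in 100 simulations of no effect.

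One hypothesis was written before its test. If gene copies near the replication origin were lost as growth stopped, changes between OD5.0 and OD5.4 would rise with distance from the first tag number. The rank correlation was -0.188, against the predicted sign, and lay within the middle 95% of all 2875 circular shifts of the tag order (exact p = 0.126, two-sided, adjusted p = 0.296 over 9 comparisons). The 719 tags nearest the first number had a median log2 change of 0.59 and the 718 farthest -0.16.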
